A study of Homo sapiens with 7 samples.

How the data were processed

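Gene expression was measured on 7 single-colour microarrays hybridised with Cy3-labelled material from Daoy cells, an established human medulloblastoma line grown in a MEM-type medium with serum and antibiotics. The labels give 1 group, with no treatment and no second condition. They assign the arrays to 2 biological replicates, 3 arrays to replicate 1 (arrays 1, 2 and 4) and 4 arrays to replicate 2 (arrays 1 to 4). An array 3 of replicate 1 was not analysed here. Per the design text of the series, each biological replicate was hybridised to an array of its own that carries 4 samples side by side, so the culture and the slide cannot be told apart. RNA was extracted with TRIzol and purified again on RNeasy columns, and it was labelled by Klenow extension from Cy3-coupled 9mer primers, per the labels' protocols. Arrays of one biological replicate were treated as technical repeats of 1 sample, so that a level has n = 2 and a p-value between the replicates measures the spread between arrays only.

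The deposited values are log2 intensities, 1 per array for each of 24000 rows named by a RefSeq accession. The submitters' processing notes name RMA, a method that corrects background, normalizes between arrays by quantiles and summarises the probes of a gene, and limma, both without a version. The base of the logarithm was not stated and was taken to be 2 by the convention of RMA and the range of 5.25 to 15.46. The sorted columns were equal within 0.002, so the arrays had been quantile normalized before deposit, and every array had a median of 8.15. The genome build and the annotation behind the rows are not given in the sources used here. The deposited table held no detection call and no single-probe values, so neither the background of each array nor disagreement between the probes of a row was examined. An intensity also depends on how well its probes hybridise. Intensities served to pick single genes to name, but levels were compared between genes only over lists, and a low intensity was not read as a missing transcript.

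Rows were named by their accession, without its version, through a RefSeq gene table of the assembly GRCh38.p14. Of the rows, 19125 matched 1 symbol, 0 matched several and 4875 matched none, of which 2705 were predicted (XM) transcripts and 2170 were NM transcripts. Unmatched rows entered the tests over all rows and no statement about a gene. The named rows belonged to 17217 genes, and the rows of the 1464 genes with more than 1 row were averaged. A set of 36 gene lists (cell machinery, division, medulloblastoma subgroups, neural and mesenchymal cells, other tissues and culture states) was fixed before the data were examined. Of their 861 entries, 849 were measured, 25 of them through an older symbol.

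Levels were the mean of the 2 replicate means, with the SD over the replicates. The level of a list was the percentile of its median among all named genes, tested against 10000 random gene lists of the same size (two-sided permutation, Benjamini-Hochberg over the 36 lists). The smallest p that these permutations can give is 1e-04. This test resamples genes, so it describes these arrays. Background was the 95th percentile of 364 olfactory receptor genes, which had a median of 5.79, and came to 7.54. The replicates were compared row by row with limma (lmFit and eBayes, replicate 2 minus replicate 1, Benjamini-Hochberg threshold 0.05), and genes in the same way after their rows were averaged. List differences were tested with limma's camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation. Intervals of a list's median difference are 95% bootstrap intervals over its members (10000 draws). On simulated data for this comparison, with 200 of 24000 rows changed, the limma step called 23% of the rows changed by 0.5 and 83% of those changed by 1, along with 5 unchanged rows. In the data 11701 of 24000 rows passed, which makes the Benjamini-Hochberg threshold looser than in the simulation. The simulated shares therefore do not give the share of real differences that were missed here. The number of arrays limits the precision of each value.

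Same-numbered arrays of the 2 replicates deviated together from their replicate means. The correlation across rows was 0.21 for array 1, 0.35 for array 2 and 0.40 for array 4, each the highest of that array of replicate 1 with any array of replicate 2. The array number was therefore taken to pair the arrays, by this check and not by a statement in the labels. What the number stands for was not tested. A fit with the array number as a block was run beside the unblocked one.

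Genes to be named were set by a rule before the data were examined. It took, for each list, the 3 measured members with the highest mean level and the 1 with the lowest, then a fixed set of 17 neural, tumour and reference genes, the 10 genes with the highest mean level, and for the replicate difference the 10 largest differences in each direction among genes past the threshold whose arrays did not overlap. Some genes and 1 list that the rules take are not reported here, and that list is left out of the plots. Genes named outside this rule are said to be chosen after their values were seen. The alternatives tried were leaving out a replicate or an array, other backgrounds, other summaries of rows and lists, filters on dim rows, array weights, an intensity trend with a robust prior, a minimum difference, and a further quantile or median step. Calculations used R 4.3.3, limma 3.58.1, statmod 1.5.0, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.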

Results

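Expression in Daoy cells was profiled on 7 arrays, 3 from biological replicate 1 and 4 from biological replicate 2. The design holds 1 untreated state of 1 cell line, so the arrays give which genes these cells express and how far the 2 replicates, each on a slide of its own, differ. Values are log2 intensities with a median of 8.15 on every array. Levels are given with the SD over the 2 biological replicates (n = 2), and a level was called above background when it exceeded 7.54, the 95th percentile of olfactory receptor genes, which are read here as not expressed.

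The machinery of protein synthesis and of central metabolism were among the brightest gene groups in Daoy cells. The 75 measured cytosolic ribosomal protein genes had their median at percentile 97.9 of all named genes, and glycolysis stood at percentile 97.9, translation factors at percentile 96.9, cytosolic chaperones at percentile 96.8 and aminoacyl-tRNA synthetases at percentile 95.9. The spliceosome followed at percentile 94.3, the proteasome at percentile 94.1 and nuclear-encoded oxidative phosphorylation at percentile 83.5. All 8 of these lists lay above random lists of their size, with an adjusted p of 3e-04 each, the smallest that the permutations can give after adjustment. Single genes of high intensity were RACK1, a protein of the small ribosomal subunit, at 15.40 ± 0.01, the elongation factors EEF2 (15.19 ± 0.26) and EEF1G (15.07 ± 0.06) and the ribosomal protein RPL7A. GAPDH of glycolysis (15.11 ± 0.21) and the cytoskeletal actin ACTB (15.04 ± 0.22) had high intensities too, and the order of such genes is not read as an order of transcripts. Further glycolytic enzymes were ENO1 at 14.93 ± 0.13 and PKM at 14.35 ± 0.20, and the ATP synthase subunit ATP5F1B stood at 14.37 ± 0.04. Of the 276 genes in these 8 lists, 15 were at or below background, among them the ribosomal protein RPLP0 at 6.0 ± 0.03, the respiratory chain subunit NDUFA8 at 6.07 ± 0.29 and the chaperonin subunit CCT5 at 7.52 ± 0.22. Such genes are used by every cell, so a value at background on these arrays also occurs for transcripts that are present.

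Genes of cell division were expressed almost throughout. All 34 measured genes of mitosis were above background, with their median at percentile 83.6 (adjusted p = 3e-04), and 33 of 34 genes of DNA replication were, at percentile 79.8 (adjusted p = 0.000771, permutation test). The mitotic kinase PLK1 stood at 13.49 ± 0.21 and CDC20, an activator of the anaphase-promoting complex, at 13.17 ± 0.22. The helicase subunits MCM7 and MCM3 reached 14.46 ± 0.23 and 13.37 ± 0.52, and the sliding clamp PCNA reached 12.73 ± 0.21. NDC80 of the kinetochore was at 8.45 ± 0.41 and the replication protein RPA3 at 7.26 ± 0.11. NDC80 lay at 6.09 on 1 array of replicate 2 and between 8.46 and 9.12 on the others.

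Genes of mesenchymal cells and extracellular matrix stood out among the cell type lists. Of the 33 measured members, 32 were above background, and their median lay at percentile 95.8 (adjusted p = 3e-04, permutation test). Among them were the secreted matrix protein TGFBI at 15.33 ± 0.06, the collagen chain COL1A1 at 14.80 ± 0.08, the matricellular protein CCN1 at 14.39 ± 0.24 and the hyaluronan receptor CD44 at 12.49 ± 0.63. The member at background was S100A4, at 7.14 ± 0.29 as the mean of its rows and at 8.08 from its brighter row.

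None of the 4 lists of medulloblastoma subgroup markers passed the test against random lists. Sonic hedgehog subgroup markers had 10 of 18 members above background and a median at percentile 41.9 (adjusted p = 0.521), WNT markers 7 of 15 at percentile 38.8 (adjusted p = 0.423), group 3 markers 5 of 12 at percentile 32.5 (adjusted p = 0.244) and group 4 markers 4 of 9 at percentile 32.9 (adjusted p = 0.337), all by the permutation test. Within the hedgehog list, the receptor PTCH1 was at 12.22 ± 0.16, its partner SMO at 11.89 ± 0.03 and the cyclin CCND2 at 11.96 ± 0.01. The pathway's transcription factor GLI2 was at 9.63 ± 0.44, while GLI1 (6.91 ± 0.02), ATOH1, a factor of granule neuron precursors (6.29 ± 0.15), and ZIC1 (5.87 ± 0.27) were below background. In the WNT list, the matrix glycoprotein TNC was at 15.14 ± 0.16, LEF1, a nuclear partner of beta-catenin, at 10.32 ± 0.22 and WNT16 at 5.89 ± 0.20. MYC was at 11.17 ± 0.57, and MYCN (7.02 ± 0.64) and OTX2 (7.06 ± 0.39) were below background. LHX2 of the group 4 list was at 10.22 ± 0.45, and KHDRBS2 at 5.77 ± 0.10.

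Neural genes were expressed in part. Neuronal markers had 8 of 25 members above background and lay below random lists, at percentile 27.9 (adjusted p = 0.0314, permutation test), a call that ended when the dimmest 25% of genes was removed (adjusted p = 0.0974). The members above background included the enolase ENO2 (13.00 ± 0.03), the neurofilament NEFL (11.65 ± 0.26) and the tubulin TUBB3 (10.62 ± 0.28), and CALB1 was at 5.56 ± 0.01. Neural stem and progenitor genes had 12 of 18 members above background at percentile 46.5 (adjusted p = 0.785). Among them the intermediate filament VIM stood at 15.02 ± 0.02, BMI1 at 10.38 ± 0.23, NOTCH1 at 9.91 ± 0.26 and the RNA-binding protein MSI1 at 9.52 ± 0.08. SOX2, at 7.94 ± 0.17, lay close to background in replicate 1 (7.82 against 7.79 there) and further above it in replicate 2 (8.06 against 7.24). NES (6.83 ± 0.54) and FABP7 (5.98 ± 0.36) were below background. Astrocyte markers had 6 of 11 members above background at percentile 53.7 (adjusted p = 0.803), with the glutamine synthetase GLUL at 11.36 ± 0.27, GFAP at 8.83 ± 0.10 and the water channel AQP4 at 5.70 ± 0.17. Oligodendrocyte markers had 5 of 13 above background at percentile 30 (adjusted p = 0.179), from CNP at 10.92 ± 0.96 to MOBP at 5.60 ± 0.13. The RNA-binding proteins of stem and tumour cells had 21 of 24 above background at percentile 71.9 (adjusted p = 0.0308), and their call ended without replicate 1 (adjusted p = 0.0525) and without the dimmest 25% of genes (adjusted p = 0.237).

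Markers of other tissues were mostly at background. Of 139 such genes, 24 were above it. Leukocyte markers had 2 of 27 members above background at percentile 19 (adjusted p = 0.000554), erythroid genes 1 of 15 at percentile 18.6 (adjusted p = 0.0104), liver genes 4 of 24 at percentile 14.7 (adjusted p = 3e-04), striated muscle genes 3 of 21 at percentile 22.7 (adjusted p = 0.0108) and pancreas genes 2 of 20 at percentile 12.5 (adjusted p = 3e-04), each below random lists by the permutation test. The erythroid and liver calls ended when the dimmest 25% of genes was removed (adjusted p = 0.13 and 0.0794). The exceptions included the macrophage marker CD68 at 10.12 ± 0.41, the protease inhibitor SERPINA1 at 10.68 ± 0.87, the troponin TNNT1 at 10.35 ± 0.57, the embryonic globin HBE1 at 8.61 ± 0.17 and the lipase CEL at 8.86 ± 0.14. CD3D of T cells (5.63 ± 0.04) and the clotting factor F9 (5.57 ± 0.03) were below background. Epithelial markers had 7 of 20 above background at percentile 29.5 (adjusted p = 0.0708), with the simple-epithelium keratins KRT8 at 11.80 ± 0.04 and KRT18 at 11.32 ± 0.13, the latter at 13.61 from its brighter row, and KRT1 of the epidermis at 5.53 ± 0.12. Their call as lower than random lists passed without replicate 2 (adjusted p = 0.03) and with the mean percentile (adjusted p = 0.0185). Endothelial markers had 5 of 12 above background at percentile 33 (adjusted p = 0.244), with ENG at 10.99 ± 0.91.

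Lists that follow the state of a culture ranged from the middle to the upper part of the distribution. Cholesterol synthesis had 21 of 22 members above background at percentile 77.5 (adjusted p = 0.00922), and NF-kB and inflammation 20 of 22 at percentile 78 (adjusted p = 0.00864). Heat shock genes had 11 of 14 at percentile 75.8 (adjusted p = 0.0476) and serum response genes 21 of 25 at percentile 72.6 (adjusted p = 0.0308). Without replicate 2 the calls of NF-kB (adjusted p = 0.321), heat shock (adjusted p = 0.203) and serum response genes (adjusted p = 0.234) ended. Without the dimmest 25% of genes those of cholesterol synthesis (adjusted p = 0.0887), NF-kB (adjusted p = 0.0794) and serum response genes (adjusted p = 0.237) ended, and the heat shock call also ended with the brightest row per gene or the mean percentile (adjusted p = 0.0566 and 0.0741). Genes of the amino acid and unfolded protein responses had 19 of 21 above background at percentile 71.6 (adjusted p = 0.052), and passed without replicate 2 (adjusted p = 0.03), with the mean over the 7 arrays (adjusted p = 0.0485) and with the mean percentile (adjusted p = 8e-04). Also without a call were interferon response genes 20 of 24 at percentile 62.9 (adjusted p = 0.244), replication-dependent histones 15 of 19 at percentile 59.6 (adjusted p = 0.438, and 0.0472 with the mean percentile) and hypoxia genes 12 of 19 at percentile 43.5 (adjusted p = 0.592). One array lay apart from the others for GAPDH, RPA3, NDC80, NEFL, GLUL, CCND2 and KRT18. In all, 16 of the 36 lists were called higher than random lists, 6 lower, and 14 did not pass.

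**Figure D1:**
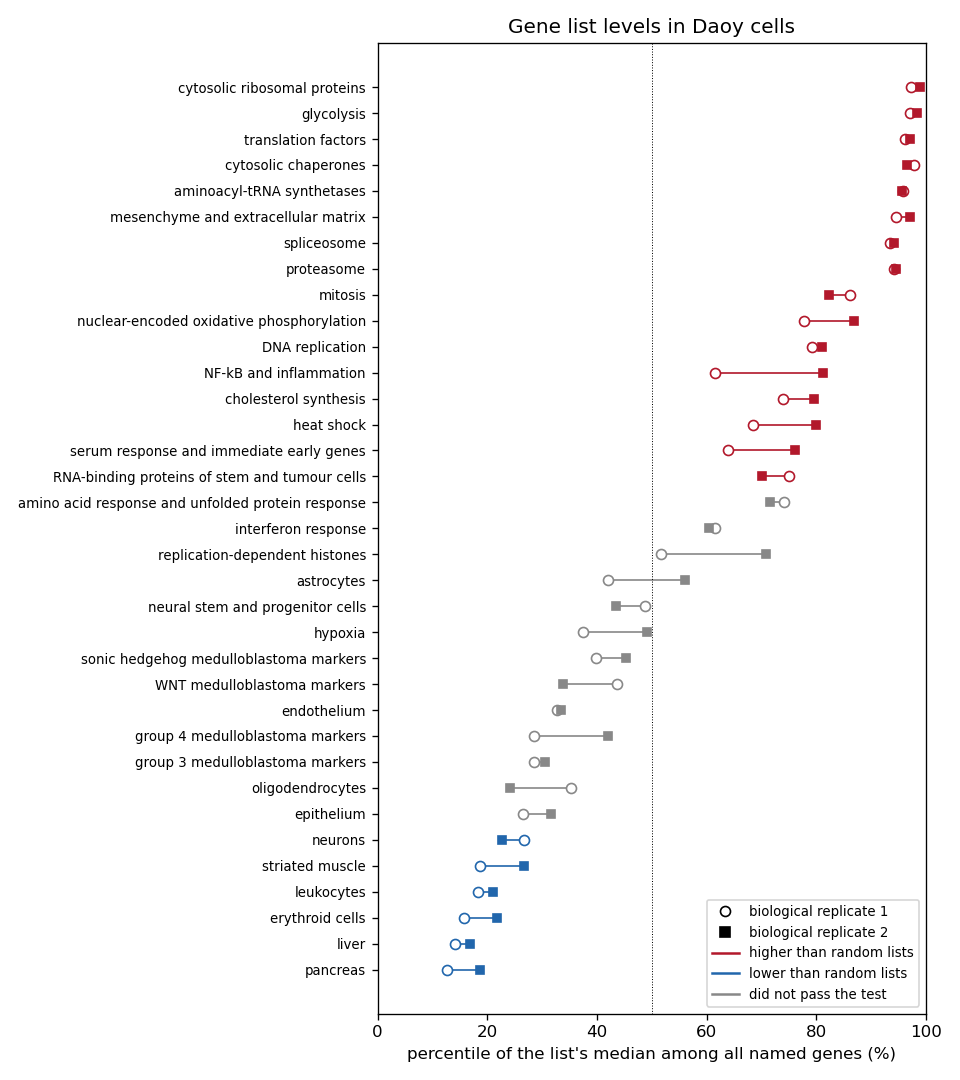
Percentile of each drawn list's median intensity among all named genes (x axis, in percent), with open circles for biological replicate 1 and filled squares for biological replicate 2, and colours for the permutation test on the mean of both. The 8 machinery lists lie at or above percentile 77.7 in both replicates, and liver and pancreas lie at or below 18.7 in both.

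Across the genome, 10430 of 17217 named genes (60.6% ± 4.66, SD, n = 2) lay above background, 57.4% in replicate 1 and 64.0% in replicate 2, each against its own background. The arrays were quantile normalized, so this gap follows mainly from the backgrounds, 7.79 in replicate 1 and 7.24 in replicate 2. It does not show that more genes were expressed in replicate 2. With the 99th percentile of olfactory receptor genes the share was 50%, and with genes of other tissues as background it was 45.4%, so the share is a function of the background chosen.

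Arrays of 1 biological replicate were closely alike, and the replicates differed by more. Pearson's r across rows was 0.985 to 0.994 over the 9 pairs within a replicate and 0.948 to 0.962 over the 12 pairs between replicates. The rows are not independent, so no p is attached. The median SD between arrays of a replicate was 0.16, and the median absolute difference between the replicate means was 0.33 on the log2 scale. A difference above 1 occurred in 10.5% of rows.

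The rises taken as largest in replicate 2 included 3 chemokines, and the falls a ribosomal protein gene. CXCL8, the neutrophil chemokine interleukin-8, rose from 9.05 to 12.43, a difference of 3.39 ± 0.11 (SE) or 10.5-fold (limma, adjusted p = 5.74e-07). The other 9 of the 10 rises had a replicate 1 mean below that replicate's background of 7.79, so they are given against it as a lower limit, and their order is uncertain. The chemokines CCL20 and CXCL2 were at least 2.55-fold and 5.11-fold higher, MAGEB10 of the cancer-testis antigen family at least 3.75-fold, the metal-binding MT1E at least 4.54-fold, the TFIID subunit TAF13 at least 4.70-fold, LRRC55 at least 3.74-fold, the semaphorin SEMA5A at least 2.34-fold, the natriuretic peptide clearance receptor NPR3 at least 2.06-fold and the carbonic anhydrase CA9, a known hypoxia target, at least 2.44-fold. The ribosomal protein gene RPS10 fell by 3.95, from 13.34 to 9.39 (adjusted p = 1.54e-06), and was read by 1 row. Differences were -3.36 for the GTPase activator ARFGAP1, -3.24 for the RNA-binding HNRNPH2, -3.09 for the thioredoxin-like TXNL1 and -2.92 for the centrosomal CNTRL. The transmembrane collagen COL23A1, the deubiquitinase USP42 and the zinc finger gene ZIM2 lay below the background of replicate 2, 7.24, there, and were at least 5.17-fold, 10.2-fold and 3.88-fold higher in replicate 1. OCIAD1 fell by 3.75 ± 0.81 (SE, adjusted p = 0.00427), with replicate 2 arrays from 6.80 on array 2 to 11.19. The histone methyltransferase EZH1 fell by 3.29 ± 1.18 (SE, adjusted p = 0.0426), with arrays of replicate 2 at 10.71, 6.01, 5.96 and 10.57, and its call ended with the array number as a block (adjusted p = 0.0632) and without any 1 of 5 arrays (adjusted p = 0.0803 to 0.105). Both genes thus hold falls of single arrays within replicate 2. Rows at least 2.5 lower in replicate 2 numbered 46, and rows at least 2.5 higher 9.

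Among the genes of the fixed set, CD44 rose by 0.89 (1.86-fold, adjusted p = 0.000178) and MYC by 0.80 (adjusted p = 7.98e-05), while GLI2 fell by 0.62 (adjusted p = 0.000738). TUBB3 rose by 0.40 (adjusted p = 0.0142, and adjusted p = 0.052 without array 1 of replicate 1). PTCH1 fell by 0.23 (adjusted p = 0.0455), a call that ended with the array number as a block (adjusted p = 0.069) and without any 1 of 6 arrays (adjusted p = 0.0586 to 0.122). NES, MYCN and OTX2 also passed the threshold (adjusted p = 0.00106, 0.000231 and 0.00303), but were below background in both replicates, so no size is given. HNRNPA1, an abundant splicing regulator, fell by 1.65 (adjusted p = 3.09e-06) as the mean of 2 rows at -3.02 and -0.29. In all, 8568 of 17217 genes passed the threshold, 4398 higher and 4170 lower, of which 856 and 689 differed by at least 1 on the log2 scale. Over all rows, 11701 of 24000 passed (48.8%), 5895 higher and 5806 lower. The arrays of the replicates did not overlap in 51.7% of rows, against 5.71% for arrays in random order. With rows at or below background removed 7715 of 13719 rows were called, and with a difference of at least 1 required as well 2453 of 24000 were. These tests compare 2 extracts, each on a slide of its own, and no condition.

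**Figure D2:**
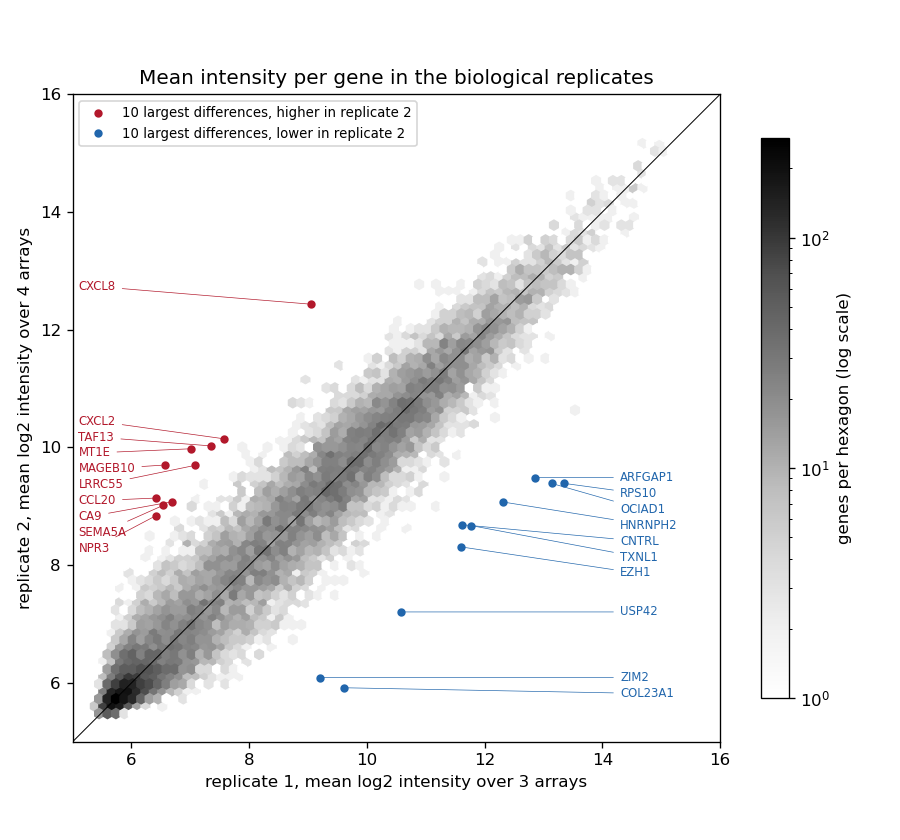
Mean log2 intensity per gene in biological replicate 1 (x axis, 3 arrays) and replicate 2 (y axis, 4 arrays), as hexagons shaded by the number of genes, with the line of equality. Red and blue points are the 10 largest rises and falls among genes past the threshold whose arrays did not overlap. They run from CXCL8 at 9.05 and 12.43 to RPS10 at 13.34 and 9.39.

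Of the 36 gene lists, 8 were shifted between the replicates, all of them higher in replicate 2 (camera with the preset correlation). The NF-kB and inflammation list had a median difference of 1.13 (95% interval 0.53 to 1.49), with 17 of 22 members higher and 2 lower at the threshold over all genes, the same numbers as adjusted over the list alone (adjusted p = 3.39e-07). Besides CXCL8, CCL20 and CXCL2 it held the monocyte chemokine CCL2, which rose by 1.62, and the mitochondrial superoxide dismutase SOD2, which rose by 0.69 as the mean of 3 rows at 0.12 (adjusted p = 0.413), 0.84 and 1.12. The lower members were the cytokine IL1B and the immediate early gene IER3, chosen after their values were seen. IER3 was at -0.44, and IL1B was below background in both replicates. Replication-dependent histones, which package newly made DNA, had a median of 1.08 (0.75 to 1.63) and 16 of 19 members higher and 0 lower, also over the list alone (adjusted p = 1.34e-08), among them H2AC20 (0.72) and H2AC18 (0.75). Whether probes of the histone members share sequence was not examined, so these members may not be independent readings. Serum response and immediate early genes were 0.70 higher (0.39 to 0.94), with 19 of 25 members up and 3 down, or 21 and 3 adjusted over the list alone (adjusted p = 5.89e-05), and IER2 rose by 0.84 and CCN2 by 0.71. This list shares 1 gene with the NF-kB list and 2 with the mesenchyme and extracellular matrix list. Cytosolic ribosomal proteins were 0.49 higher (0.34 to 0.73), with 49 of 75 members up and 2 down, also over the list alone (adjusted p = 2.79e-09). The lower members were RPS10 and RPL30, the latter (-1.52) chosen after its value was seen. With an estimated correlation these 4 lists kept their call, at adjusted p = 0.038 for NF-kB, 0.0249 for histones, 0.038 for serum response and 0.0128 for ribosomal proteins.

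The other 4 called lists lost their call with an estimated correlation. Cholesterol synthesis was 0.60 higher (0.31 to 0.84), with 15 of 22 members up and 0 down, or 16 and 0 adjusted over the list alone (adjusted p = 3.14e-05, and adjusted p = 0.0688 with an estimated correlation). Its member DHCR7 rose by 1.08, and HSD17B7 was below background in replicate 1. Mesenchyme and extracellular matrix genes were 0.38 higher (0.13 to 0.73), with 18 of 33 up and 6 down, also over the list alone (adjusted p = 0.0221, and adjusted p = 0.169 with an estimated correlation). This call also ended without array 2 of replicate 1 (adjusted p = 0.0542) and with genes at background removed (adjusted p = 0.0582). Oxidative phosphorylation was 0.36 higher (0.17 to 0.58), with 28 of 49 up and 5 down, or 28 and 6 adjusted over the list alone (adjusted p = 0.000603, and adjusted p = 0.169 with an estimated correlation), where the cytochrome oxidase subunit COX4I1 rose by 0.55 and the ATP synthase subunit ATP5F1A fell by 0.35. Glycolysis was 0.33 higher (0.08 to 0.52), with 11 of 18 up and 0 down, also over the list alone (adjusted p = 0.0146, and adjusted p = 0.169 with an estimated correlation), among them the aldolase ALDOC, which was below background in replicate 1 and at least 3.74-fold higher in replicate 2.

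Lists of cell division, tumour subgroups and neural cells did not pass the test, and adjusted p over all uncalled lists ran from 0.11 to 0.957. DNA replication had a median difference of -0.002 (-0.07 to 0.16) with 8 of 34 members up and 6 down, and mitosis 0.19 (-0.13 to 0.29) with 11 up and 7 down of 34. The hedgehog, WNT, group 3 and group 4 lists had medians of -0.03, -0.23, -0.08 and -0.24. Neural stem genes had a median of -0.02 while camera's direction for them was upward (adjusted p = 0.957). Heat shock genes had a median of 0.39 (-0.02 to 0.64, adjusted p = 0.11) and passed once the dimmest 25% of rows or all those at background were removed (adjusted p = 0.0319 and 0.0295). Hypoxia genes had a median of 0.15 (-0.12 to 1.08, adjusted p = 0.11), with 9 of 19 members up and 3 down. Differences were related to gene length across genes, which are not independent replicates (Pearson's r = -0.228, Spearman's rho = -0.235), with short genes higher in replicate 2. The median gene length of the called lists ran from 0.527 kb for histones to 36.2 kb for mesenchyme and extracellular matrix. Other splits of the 7 arrays into 3 and 4 gave up to 10 called lists.

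**Figure D3:**
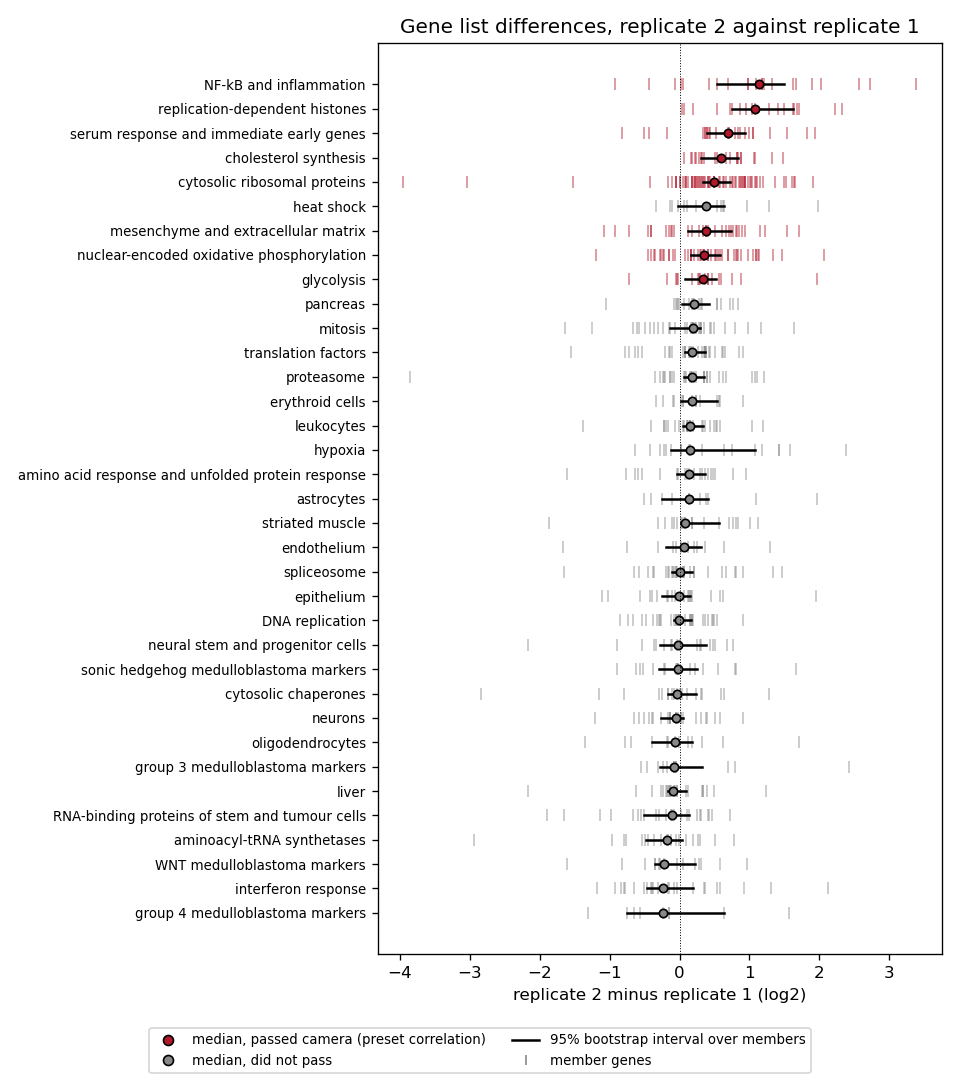
Difference of replicate 2 minus replicate 1 (x axis, log2) for the members of each drawn list (ticks), with the list's median (circle) and its 95% bootstrap interval (bar), red where camera with the preset correlation passed. The 8 red medians lie between 0.33 and 1.13, and the median of DNA replication lies at -0.002.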

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

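The tests of failed probe sets in this part were chosen only after the result was seen, as was that of a weak position on array 3, and that of a weak position on array 2 was fixed before. Each of 100 named genes and 36 lists was searched over the 7 arrays for 1 array set apart from the others, by the size of its gap to the nearest array relative to the whole range (Dixon's test). A rule of this kind marks about 1 in 20 groups by chance where all values come from 1 normal distribution. The 7 arrays come from 2 replicates that differ, so this rate need not hold here. Of 136 items 7 were marked, all of them genes.

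NDC80 stood at 6.09 on array 3 of replicate 2, against 8.46 to 9.12 elsewhere. On array 2 of replicate 1, GAPDH was low (14.41, others 15.12 to 15.36), as were NEFL (11.11, others 11.62 to 11.90) and GLUL (10.74, others 11.34 to 11.73). On array 4 of replicate 1, KRT18 was low (11.04, others 11.30 to 11.50). RPA3 was high on array 1 of replicate 2 (8.07, others 6.92 to 7.40), and CCND2 was low on array 4 of replicate 2 (11.85, others 11.96 to 12.01).

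Falls of single arrays were a wider pattern of replicate 2. A fall of at least 3 on the log2 scale from the other arrays of the replicate occurred in 60 of 24000 rows, 20 times on array 2 and 49 times on array 3 of replicate 2 and 0 times on any array of replicate 1. RPL35A, PSMD1 and TPM4, chosen after their values were seen, show these falls: RPL35A lay at 6.15 and 7.86 on those arrays and at 13.45 or above on the rest, and PSMD1 and TPM4 reached 6.08 and 6.31 on array 3. Rises of that size were counted 24 times, in 15 rows and in replicate 2 alone, and 3 of these rows held no fall. In the others, arrays 2 and 3 both lay low, so arrays 1 and 4 counted as rises only against them. RPL35A, for example, was at 14.36 and 14.39 on arrays 1 and 4 of replicate 2, beside 13.45 to 14.22 in replicate 1. EZH1 (6.01 and 5.96 on arrays 2 and 3) and OCIAD1 (6.80 on array 2) hold such falls too. A weak position shared by both slides stays open. Of the 20 falling rows of array 2, 0% were at least 1 lower on array 2 of replicate 1. This would argue against a shared position only if the array number stands for it, which the labels do not state. For the 49 falls on array 3, 0 arrays numbered 3 were analysed in replicate 1. Probe sets that failed on single arrays stay open as well, since only 8 falling rows belong to a gene with another row, which was at least 1 lower on that array in 0 of them, too few to decide. No biological explanation was tested, as the arrays of a replicate are technical repeats.

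Large differences between the replicates also leaned downward, with 46 rows at least 2.5 lower in replicate 2 and 9 at least 2.5 higher. At a cut of 2 there were 112 lower and 69 higher. Among called rows at a cut of 1 the lean was the other way, with 1150 lower and 1303 higher. EZH1 and OCIAD1 are among the rows at least 2.5 lower, so the single-array falls make up part of the lean. Among 25 rows at least 2 lower whose gene has another row, the other rows were at least 1 lower in 7, with a median of -0.40 against -2.67 for the rows themselves. Rows picked for a large difference exceed their gene's other rows in either direction, and only 4 rows at least 2 higher had other rows, at least 1 higher in 0, too few to compare (Fisher's exact p = 0.546). Probe sets that failed over the whole of slide 2 could account for part of these falls, and rows of different transcripts of a gene can differ truly, and neither is decided. RPS10 has 1 row and was not tested in this way.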

How the results depend on the processing

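Leaving out arrays 2 and 3 of slide 2, removing rows with single-array falls and removing the length trend were chosen after seeing the data, and the other settings before. A further quantile or median step moved next to nothing on values already quantile normalized, so those settings test nothing. The share of genes above background was 50% with the 99th percentile of olfactory receptors, which is stricter by construction. It was 45.4% with genes of other tissues as background, a set whose cut was higher by its values in these data. Without 1 replicate it was 57.4 to 64%. Called rows (11701 of 24000) were 7715 of 13719 without background rows, where fewer rows were tested and a larger share of them passed. With a minimum difference of 1, which fewer rows could pass, they fell to 2453. They were 9980 to 11084 without 1 array, 9271 without arrays 2 and 3 of slide 2 and 11766 without rows with falls. After the length trend was removed, 9369 of the 19125 rows with a gene length were called. With the array number as a block, 12919 rows and 8 lists were called, and the block ended the calls of EZH1 (adjusted p = 0.0632) and PTCH1 (adjusted p = 0.069) and of no other gene named for its difference. PTCH1 also lost its call without the dimmest 25% of rows (adjusted p = 0.0519), without any 1 of 6 arrays (-0.206 to -0.246), without arrays 2 and 3 of slide 2 (-0.256) and with the length trend removed (-0.119), and TUBB3 without array 1 of replicate 1 (0.364) and without arrays 2 and 3 of slide 2 (0.401). EZH1 also lost its call with array weights, with an intensity trend and without any 1 of 5 arrays (-2.51 to -3.38). Called lists were 4 with an estimated correlation and 7 to 8 without 1 array, the 7 without array 2 of replicate 1, where mesenchyme genes lost their call (adjusted p = 0.0542). The median replicate difference was 0.415 above background only. The cause of these changes was not tested unless stated.

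Signs turned only in lists without a call. Levels crossed the 50th percentile for astrocytes (41.9 without replicate 2, 43.8 as mean percentile, 41.3 without the dimmest 25%), hedgehog markers and hypoxia (51.2 each as mean percentile) and histones (48.8 without the dimmest 25%). Without replicate 1 the astrocyte level was 56, on the same side as its main value of 53.7. Differences turned without background rows in hedgehog (0.067), group 3 (0.687), neuron (0.164), leukocyte (-0.404), endothelial (-0.044) and liver lists (0.153), and without the dimmest 25% in epithelium (0.127). Under the block they turned in spliceosome (-0.009), DNA replication (0.008), oligodendrocyte (0.001) and epithelial lists (0.006), and with the length trend removed in spliceosome (-0.009) and DNA replication (0.065). Without arrays 2 and 3 of slide 2 they turned in DNA replication (0.034), oligodendrocytes (0.03) and epithelium (0.027). Without 1 array the medians that turned at least once ranged from -0.013 to 0.072 (spliceosome), -0.059 to 0.054 (DNA replication), -0.092 to 0.002 (hedgehog), -0.044 to 0.028 (neural stem), -0.04 to 0.062 (epithelium), -0.111 to 0.02 (chaperones) and -0.187 to 0.031 (oligodendrocytes). The cause was not tested. Genes at background limit what can be said of low transcripts.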

Other observations

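Beyond the fixed lists, 8 gene families were examined that were chosen after the values were seen, so their tests are descriptions. Metallothioneins, small metal-binding proteins, had 7 of 9 members higher in replicate 2 and 0 lower, with a median of 1.01 (camera, adjusted p = 0.000573 over the 8 families, and adjusted p = 0.0812 with an estimated correlation). Clustered protocadherins, neural adhesion molecules, had 32 of 53 members lower and 4 higher, with a median of -0.42 (adjusted p = 1.28e-06, and adjusted p = 0.0812 with an estimated correlation). Their probes can share sequence, so they are not independent readings. Zinc finger (ZNF) genes had 152 of 429 lower and 55 higher (adjusted p = 0.00382, and adjusted p = 0.0812 with an estimated correlation), and ubiquitin-specific proteases 17 of 42 lower and 4 higher (adjusted p = 0.0054, and adjusted p = 0.165 with an estimated correlation). The median of the latter, which have a median length of 75.8 kb, went from -0.27 to -0.14 once the trend with gene length was removed, and that of metallothioneins from 1.01 to 0.73, while that of protocadherins (110 kb) went from -0.42 to -0.48 and that of ZNF genes stayed at -0.21. Mitochondrial ribosomal proteins had 33 of 77 higher and 10 lower (adjusted p = 0.00507, and adjusted p = 0.133 with an estimated correlation).

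By level, 31 of 38 HOX genes, which pattern the body axis, were above background, with their median at percentile 53.8. Of the MAGE family of cancer-testis antigens 16 of 28 were, with their median at percentile 45.1. Among all named genes the share above background was 60.6%. The 3 classical HLA class I genes had their median at percentile 98.9. None of these 3 families passed the test between the replicates (adjusted p = 0.494, 0.2 and 0.452).

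The tests of chance, gene length, single-array falls and slide for the replicate difference were fixed before their results were seen, and the test of S phase was chosen afterwards. Over the 35 splits of the 7 arrays into 3 and 4, the number of called rows was as large as 11701 in 1, the real one, and the highest of the others was 0. The number of called lists was at least 8 in 4 of the 35 splits, the highest of the others being 10. Splits with 0, 1 and 2 arrays of replicate 1 in the group of 3 gave 6 to 7, 0 to 3 and 4 to 10 lists. The array numbers were taken to pair the arrays, and only 8 splits part as many pairs as the real one, too few for a share under 5%. The highest of the others among them gave 0 rows and 9 lists. All splits but the real one mix the replicates, so that the replicate difference enters the spread within their groups, and the arrays are technical repeats of 2 samples.

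The 8 lists called with the preset correlation, 4 of which kept their call with an estimated one, were weighed against technical sources. A trend with gene length is argued against as the whole cause, since all 8 kept their call (preset correlation) and direction once the trend was removed from each array. It stays open as a part of the shifts. Removal lowered the medians of all called lists but mesenchyme, which went from 0.38 to 0.45. Serum response genes went from 0.70 to 0.48 and oxidative phosphorylation from 0.36 to 0.25. The calls of all 8 lists were also kept after the genes with single-array falls were removed, but this removal tests little. The falls lower replicate 2 while the 8 lists were higher there, so falls of their members would work against these shifts. A difference in slide, labelling or hybridisation stays open, because 0 slides carried both replicates, and it cannot be told apart from a difference between the cultures. For the histones, a larger share of cells in S phase would raise DNA replication genes too. The upper bound of their median difference was 0.161 beside a histone median of 1.08, but 8 of 34 members rose and 6 fell and the rise needed is not known, so S phase stays open. A true difference between the cultures stays open and untested.

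An undecided result concerns MTAP, which is often lost in tumours. MTAP stood at 5.59 ± 0.01 (SD, n = 2), within a run of 10 neighbouring genes at or below background, after members of large gene families were set aside, that begins with FOCAD (5.54 ± 0.06). The region was chosen after its values were seen, and so was the test against chance, while that against other runs was fixed before its result. A run as long occurred in 39.9% of 1000 shuffled gene orders, and the real order held 10 other runs as long. Chance or neighbours that are silent together could thus account for a run of this length. Both tests count genes at or below background, as 37% of the genes in order were, and do not weigh how low they lie. They therefore cannot decide whether a segment was lost.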
